A study of Drosophila melanogaster with 6 samples.

How the data were processed

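Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on Drosophila melanogaster collected 12 hours after the white prepupal stage. Per the labels, the strain is USP-GFP, with a transgene of the usp genomic coding region. The labels' protocols instead name y; bw cn sp flies, and which of the 2 holds for the chromatin is not settled by the sources used here. Per the labels' protocols, cultures were kept at 25 °C and the collected animals were cross-linked in 1.8% formaldehyde for 15 min. The series holds 3 libraries precipitated with a rabbit polyclonal antibody against GFP and 3 libraries of input DNA, grouped by their titles. The replicate numbers 1 to 3 occur in both groups.

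The only processed file is a list of regions for the whole series. Per the file headers, the regions were called with MACS on FlyBase release 5 of the genome. Per the submitters' processing notes, CASAVA 1.7.0.2 and 1.7.0.3, BWA and MACS2 were used with the build BDGP5. The calling threshold, the other parameters, and whether the 3 ChIP libraries were pooled before calling or combined afterwards are not given in the sources used here. The list has no value per library, so no error between replicates can be given, and no difference between libraries was tested. Library sizes are not in the list, so the sequencing depth of each library is unknown.

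The other deposited values in the list are the start and end of each region. Starts were read as counting from 0, because 1 region starts at 0 and the smallest difference between end and start is 200 bp, and 1 was added to each printed start. The file headers do not say which quantity of the peak caller the deposited score is. It had first been taken as a caller score of unknown kind. After the values had been examined it was read as the −log10 p-value of the authors' peak caller, from the values alone. Many regions share identical scores, and many of these, though not all, follow the upper tail of a Poisson distribution with a single background mean. The background was fitted by a search from 20 to 130 reads over scores under 40, and the fit was made separately on 2L with 2R and on 3L with 3R. Both fits gave a background of 63.82 reads per position. With the value from 2L and 2R, 42.6% of the 1549 scores on 3L and 3R lay within 0.01 of a step, against 6.32% after random shifts of the scores, averaged over 100 draws. For a region on a step, the read pileup implied by the step was divided by the background to give a fold. The score does not tell whether the caller counted the observed pileup itself in the tail, which moves the implied pileup by 1 read.

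Regions per Mb were computed over the length from the first to the last region of an arm, since no chromosome lengths of release 5 were used here. Each density has an exact Poisson 95% interval. Densities were compared over arms by a Monte Carlo multinomial test with 100000 draws, whose smallest p is 1e-05, and single arms against 2L, 2R, 3L and 3R by an exact binomial test. Because regions are clustered, density ratios also have a 95% bootstrap interval, added after the densities had been seen, from 2000 draws of 500 kb blocks (100 kb on chromosome 4). Clustering was tested against 1000 random placements of the same widths on the same arm without overlap, two-sided, with a smallest p of 0.002. Positions were drawn uniformly from the start of the arm to the end of its last region. Median scores were compared by permutation with 20000 draws, two-sided, with Benjamini-Hochberg adjustment over 5 comparisons. Width and score were correlated across regions, with 100000 permutations for the full list and 20000 within arms or Uextra and for each alternative setting. Shares have Wilson 95% intervals. The binomial, multinomial, Fisher and permutation tests of density, score and steps treat regions as independent, so their p-values do not allow for clustering. All intervals cover counting error or the spread along the genome, not the spread between animals or libraries.

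The design, the first set of processing alternatives and the rule for named items were fixed before the data were examined. The rule names the 20 regions with the highest score where no gene names can be attached. Tests of distance to transcription starts, of gene lists and of sequence motifs had been planned. They were not run, because the gene table used here is of release 6, the regions are on release 5, and no genome sequence was used. No region is therefore given a gene, an exon or an intron. Chosen after the values were seen were the grouping of sequences, the comparisons of median scores, the single-arm binomial tests, the highest regions of each arm, the clusters, the bins, all analyses of the background steps, and further processing alternatives. The labelling of density ratios under each alternative was also made stricter after results had been seen, so that a ratio whose bootstrap interval includes 1 counts as weakened.

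The code was tested on simulated data. With 3218 regions placed at random the permutation test of neighbours gave p = 0.398 and the X ratio came out at 0.96 where equal density had been simulated. With 3009 clustered regions and an X ratio of 0.5 it gave a neighbour p of 0.00995, the smallest that simulation's placements could give, and an X ratio of 0.51. A background of 50 reads was recovered as 50 from 2215 simulated scores. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.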

Results

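Ultraspiracle (USP) is the fly relative of the vertebrate retinoid X receptors and the DNA-binding partner of the ecdysone receptor EcR. It was the target of this ChIP-seq 12 hours after the white prepupal stage, near the time at which the prepupa becomes a pupa. Per the labels, the factor was precipitated with an antibody against GFP from the strain USP-GFP, and input DNA was sequenced beside it. The labels' protocols name other flies, and this is not settled. Input DNA is the only control in the series, so the list alone does not show that each region is bound by USP. The list holds 3791 regions with a median width of 351 bp and 1777 kb of covered sequence. The 6 chromosome arms 2L, 2R, 3L, 3R, X and 4 held 3262 of them, or 86.0% (95% interval 84.9 to 87.1%). The remainder lay in the unplaced collections Uextra (479 regions) and U (26 regions), in the Het sequences of mapped heterochromatin (20 regions) and in the mitochondrial genome (4 regions). The list has no value per library, so none of the following carries an error between replicates.

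On the arms, regions were narrow and of moderate height. Their median width was 346 bp with quartiles of 256 and 542 bp, and their median score was 12.8 with quartiles of 10.2 and 17.4, the score being read as the −log10 p-value of the peak caller. The width and the score rose together across regions of the 6 arms (Spearman rho 0.65, Pearson r 0.63, both permutation p = 5e-05, the smallest the draws allow). The relation across all 3791 regions was looser (rho 0.53, r 0.23, both permutation p = 1e-05), with r at 0.36 when the log10 of the score was used, and within Uextra rho was 0.41 and r 0.45, both with a permutation p of 5e-05. Regions are not independent replicates. Width and score come from the same call of a region, so the permutation test does not show a relation beyond the calling itself. On 2L, 2R, 3L and 3R, 1224 of 2868 regions had a score on the steps set by a single background of 63.82 reads. The read pileup implied by those scores was a median 2.03 times the background, with quartiles of 1.90 and 2.24 and a range of 1.66 to 6.00.

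The first comparison asked whether USP-GFP regions were spread evenly over the chromosomes. The X carried 15.1 regions per Mb (95% interval 13.5 to 16.8, 335 regions), while 2L, 2R, 3L and 3R together carried 30.0 per Mb (28.9 to 31.2, 2868 regions). The ratio of X to these arms was 0.50, with a bootstrap interval of 0.37 to 0.65 and an exact binomial p of 1.2e-38. The small chromosome 4 was denser, at 50.9 regions per Mb (38.8 to 65.7, 59 regions), a ratio of 1.696 (1.20 to 2.22, exact binomial p = 0.00017). Among the 4 large autosomal arms the densities were 29.8 on 2L, 29.2 on 2R, 32.6 on 3L and 28.6 on 3R. These 4 did not differ past the threshold (Monte Carlo exact multinomial test, p = 0.0552), while all 6 arms together did (p = 1e-05, the smallest the draws allow). Median scores were 13.6 on the X, 12.7 on 2L, 2R, 3L and 3R and 12.9 on chromosome 4. Neither difference from the large autosomal arms passed the adjusted threshold (adjusted permutation p = 0.056 for the X and 0.804 for chromosome 4). Among regions with a score of at least 21.57, a limit set after the values were seen, the ratio was 0.70 for the X with an interval that includes 1 (0.43 to 1.02, exact binomial p = 0.0062). For chromosome 4 it turned to 0.79 (0 to 1.75, exact binomial p = 0.823).

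**Figure D1:**
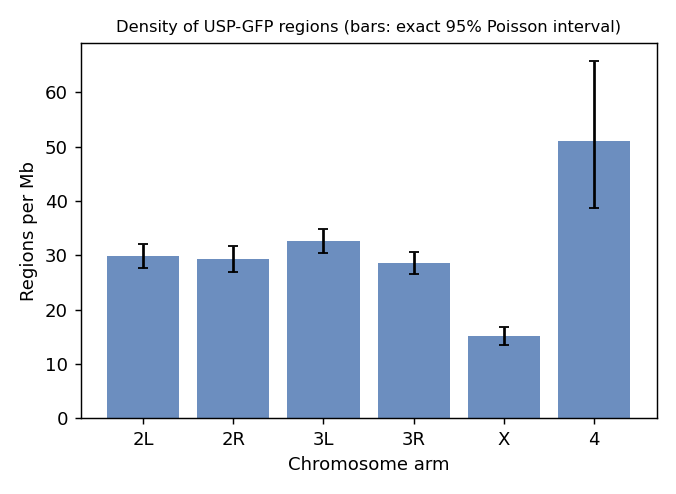
Regions per Mb on each chromosome arm, counted over the length from the first to the last region of the arm; error bars are exact 95% Poisson intervals. The X stands at 15.1 regions per Mb, below the interval of every other arm, and chromosome 4 at 50.9 above them.

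**Figure D2:**
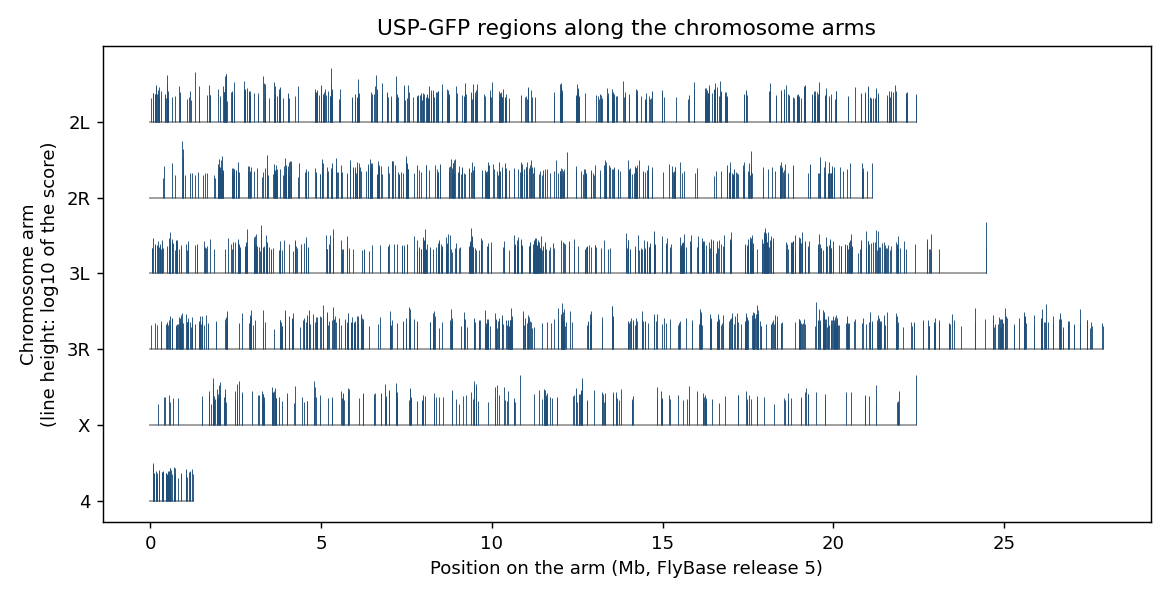
Position of each region (x axis, Mb on FlyBase release 5) on the 6 arms, with the height of each line proportional to the log10 of its score. Regions come in groups with gaps between them, and the X is more thinly covered than the large autosomal arms.

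The second comparison asked whether regions lay closer together than under uniform random placement along each arm. Such placement treats all positions as open to calls, so it does not allow for stretches where none can be made. Of the 3262 regions on the arms, 2237 or 68.6% had another region within 5 kb, centre to centre. Random placement of the same regions gave 23.1% on average and at most 26.0% in 1000 placements (permutation test of positions, two-sided p = 0.002, the smallest the placements allow). The share was 70.4% on 2L, 65.8% on 2R, 73.3% on 3L, 69.0% on 3R, 57.0% on the X and 72.9% on chromosome 4. Relative to its own random placement, the share was 4.48 times as high on the X (57.0% against 12.7%). On 2L, 2R, 3L and 3R it was 2.90 times as high (69.8% against 24.0%). The random share is larger where regions are denser, which lowers the highest ratio that can be reached. The 2 ratios therefore do not show stronger clustering on the X, and whether they differ was not tested. In bins of 500 kb the large autosomal arms held 15.1 ± 9.69 regions (SD over 188 bins), with a variance 6.21 times the mean and a range of 0 to 65. The bin with 65 regions lay on 3L from 17556763 to 18056762.

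Regions chained by steps of up to 5 kb formed 685 clusters of 2 or more, 112 clusters of 5 or more and 12 clusters of 10 or more, while 1025 regions stood alone. The largest cluster in any random placement held 8 regions. Both the clusters and the placements use the regions as listed, so pieces of a stretch split by the caller count separately. Merging regions within 500 bp left 3048 of the 3791 regions of the whole list. Cluster sizes after such merging were not computed. The cluster with the most regions spanned 28.6 kb of 3L, from 17981398 to 18010023, with 21 regions covering 18.9 kb. Its highest score was 71.95, at 17997501 to 17999225. Next to it on the side of lower coordinates lay a cluster of 9 regions, from 17954881 to 17972142. On 3R, 18 regions lay from 12047507 to 12079695, with a top score of 76.5, and 17 regions from 5164298 to 5179725, with a top score of 33.19. Another cluster on 3R, from 17762262 to 17776358, held 10 regions and reached 60.71. On 2R, 3 clusters of 11 regions each lay at 7068839 to 7092072, 7479973 to 7495674 and 7517017 to 7529975. On 2L, 10 regions lay from 5287554 to 5307483. This cluster contains the widest region of the arms, 6010 bp from 5289804 to 5295813, with a score of 161.07. The other clusters with 10 or more regions were at 158598 to 172343 and 7418341 to 7427099 on 2L and at 11235187 to 11256751 and 16152802 to 16174505 on 3L. The X and chromosome 4 had none of this size.

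**Figure D3:**
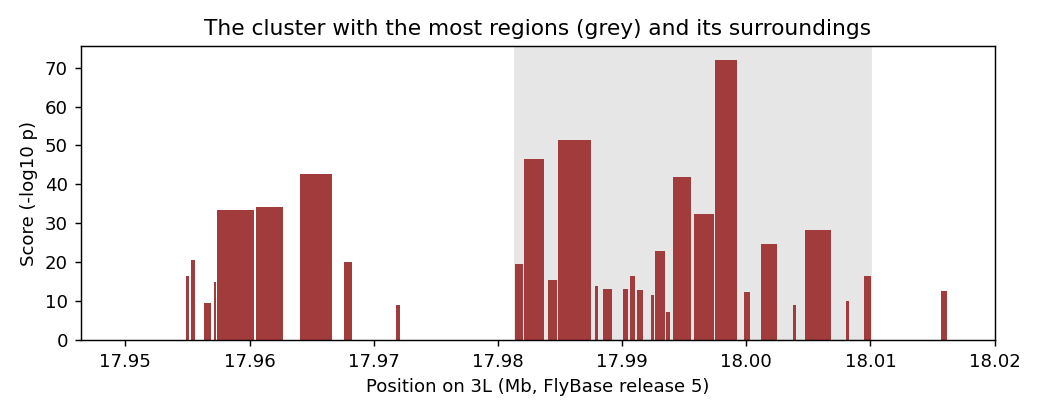
Regions on 3L around the cluster with the most members (grey, 21 regions); each bar spans a region on the x axis (Mb, FlyBase release 5) and its height is the score. The highest bar reaches 71.95, and the 9 regions of the neighbouring cluster stand to the left.

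Of the 20 regions with the highest score in the whole list, 16 lay in Uextra, 3 in U and 1 on an arm. The highest was a 554 bp region of U at 2605800 to 2606353 with a score of 715.93, followed by a 562 bp region of Uextra at 22939290 to 22939851 with 707.77. The other Uextra and U regions among the 20 scored from 203.04 to 545.74. The one on an arm was the 2209 bp region of 2R at 936663 to 938871, with a score of 200.6. The highest regions of the other arms were those of 2L at 5289804 to 5295813 (161.07), 3L at 24462044 to 24463747 (123.08), X at 10817770 to 10819781 (108.11), 3R at 19495352 to 19495843 (79.84) and chromosome 4 at 87805 to 88264 (32.11). The regions of 2R and 3L lay in the parts of these arms nearest to the centromere. Other high regions of these arms were found on 2L at 1301751 to 1302365 (110.03), on 3L at 3245754 to 3249404 (91.99), on X at 22422249 to 22422863 (106.4) and 12644515 to 12647358 (82.35), and on 3R at 12060350 to 12063357 (76.5), the last inside the cluster of 18 regions.

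The median score in Uextra was 37.2 with quartiles of 28.6 and 56.9. It was 2.91 times the median of the arms (bootstrap interval 2.79 to 3.18, adjusted permutation p = 0.00012), while the median width, 370 bp, differed little from the 346 bp of the arms. Uextra regions were unevenly spread: 242 of them (50.5%) lay from 28 Mb on, a limit set after the values were seen. Their median score was 36.5, against 39 before 28 Mb. Without the last 1 Mb of Uextra the ratio to the arms was 3.05. The 26 regions of U had a median score of 28.2, a ratio of 2.21 (1.57 to 3.53, adjusted permutation p = 0.00012). The 20 regions of the Het sequences had a median of 18.9, a ratio of 1.48 with an adjusted permutation p of 0.0036 and a bootstrap interval that includes 1 (0.93 to 2.19). In the mitochondrial genome 4 regions with scores from 40.92 to 186.16 together covered 19266 bp, or 98.5% of the length up to the end of the last one.

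**Figure D4:**
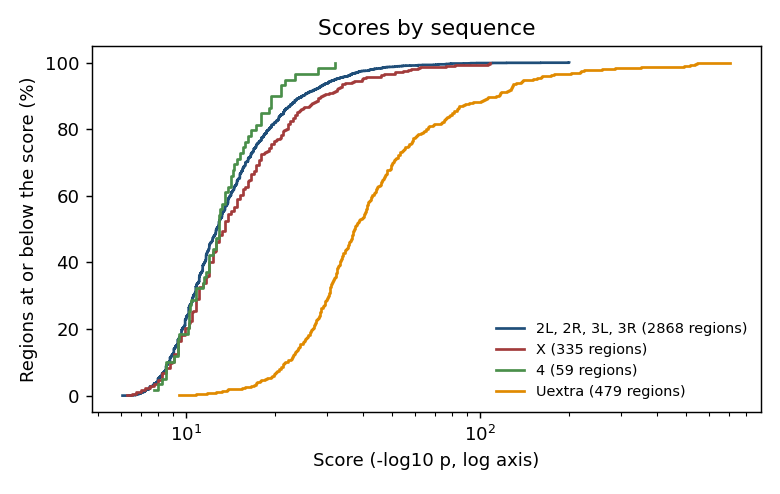
Percentage of regions (y axis) at or below each score (x axis, log scale) on the large autosomal arms, the X, chromosome 4 and Uextra. The first 3 curves run close together, with medians from 12.7 to 13.6, and the Uextra curve lies to the right, with a median of 37.2.

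Scores on the steps of the genome-wide background were not equally frequent on all sequences. They made up 89.9% of the regions on the X (95% interval 86.2 to 92.6%, 301 of 335) and 42.7% on 2L, 2R, 3L and 3R (40.9 to 44.5%), a difference of 47.2 percentage points (Fisher's exact test, p = 1.4e-66). The share was 74.6% on chromosome 4 (62.2 to 83.9%, 44 of 59), 31.9 points above the large autosomal arms (Fisher's exact test, p = 1.6e-06). Among regions on the steps, the implied pileup over background had a median of 2.05 on the X, 2.04 on chromosome 4 and 2.03 on the large autosomal arms. In Uextra 29.0% lay on the steps (25.1 to 33.2%, 139 of 479), and their median implied pileup was 3.13 times the background. Each implied pileup is fixed by the score at the single fitted background. These medians therefore restate the scores and do not compare enrichment over local input between sequences.

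**Figure D5:**
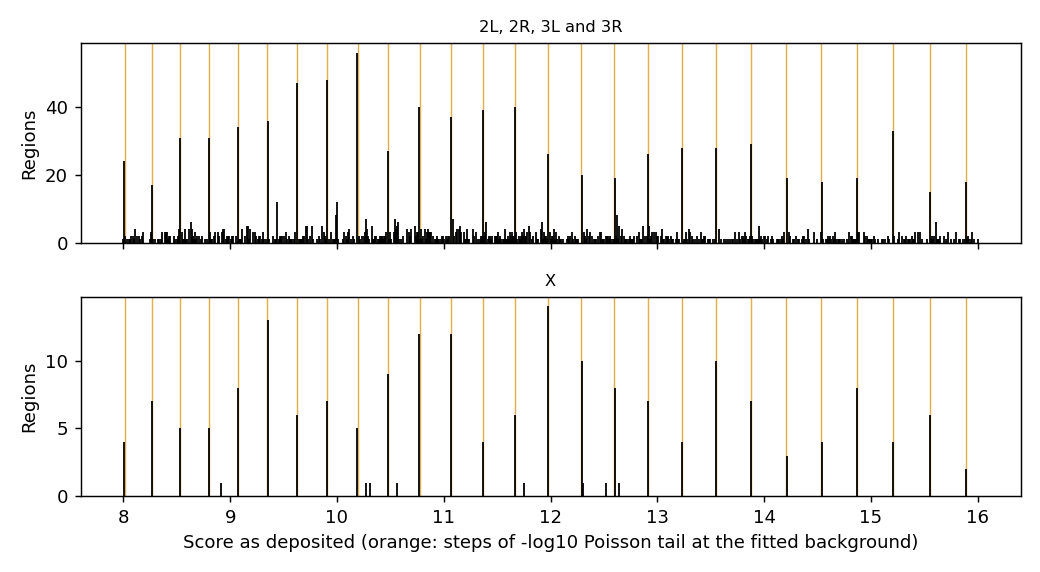
Number of regions (y axis) at each deposited score from 8 to 16 (x axis) on the large autosomal arms and on the X; orange lines mark the −log10 Poisson tail at whole read numbers for a background of 63.82 reads. On the X 89.9% of all regions stand on a line, and on the large autosomal arms 42.7%.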

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

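Of the tests in this part, those of the steps on the X and in Uextra were chosen only after the result was seen; the merging, width and clustered-against-single tests were written down before theirs, though after the list had been explored. No biological explanation was tested. The list compares no conditions, and the planned tests of transcription starts, gene lists and motifs were not run.

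Regions were listed on sequences that the comparison of arms does not use, and they stand here for that reason. There were 479 in Uextra, 26 in U, 20 in the Het sequences and 4 in the mitochondrial genome. The widest mitochondrial region runs from 1 to 15748. The Het regions include 3 with scores above 100, at 1279520 to 1281334 on 3LHet (106.88), 1518006 to 1519693 on 3RHet (106.01) and 42 to 740 on XHet (126.23). In U, adjoining regions at 5288421 to 5297530 and 5297733 to 5303521 are 9110 and 5789 bp wide, against at most 6010 bp on the arms.

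Scores in Uextra were 2.91 times those of the arms. Width is argued against as the whole cause, since regions of 200 to 400 bp gave a ratio of 3.02 (bootstrap interval 2.92 to 3.28). Missing input reads would leave the genome mean as background. They are argued against as the whole cause, by a test chosen after its result was seen. At scores from 20 to 60, 23.8% of Uextra regions lay on the background steps, against 45.8% on the arms (Fisher's exact test, p = 2.3e-11). The arms include the X and chromosome 4, where the share over all scores was higher than on 2L, 2R, 3L and 3R. Over all scores, 139 of 479 Uextra regions (29.0%) lay on the steps, and for these missing input stays open. Sequences present in many copies in the animal, or DNA of another organism, remain open, because no sequence was compared.

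The X held 0.50 times the regions per Mb of 2L, 2R, 3L and 3R. Repeated counting within autosomal clusters is argued against as the whole cause, since merging regions within 5 kb left a ratio of 0.60 (bootstrap interval 0.49 to 0.72). A smaller number of X copies in the chromatin, as a sample with males would have, is a candidate explanation: 89.9% of X regions lay on the steps of the genome-wide background, against 42.7% on the large autosomal arms, which is what a peak caller that takes the larger of the local and the genome-wide background would give where input is thin. The step share does not single out this cause, since it was also raised on chromosome 4 (74.6%), which was denser in regions, and the sex of the animals is not given in the sources used here. A lower number of USP sites on the X stays open and was not tested.

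Regions lay closer together than random placement. Splitting of broad stretches by the caller at gaps of up to 500 bp is argued against as the whole cause. After merging within 500 bp, 51.5% still had a neighbour within 5 kb, above the 20.9% of the highest random placement. Merging at this distance cannot undo splits with wider gaps, so those stay open. Stretches rich in input DNA would put clustered regions on the steps less often than single ones. On 2L, 2R, 3L and 3R this deficit was not seen. Clustered regions lay on the steps 1.19 percentage points more often (43.0% against 41.8%, Fisher's exact test, p = 0.565). The difference is within chance and a small deficit is not excluded, so this cause cannot be told apart from others.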

How the results depend on the processing

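Of 25 alternatives with a test and an outcome not fixed by construction, 22 left direction and call as they were. All the others were density ratios of the X or of chromosome 4. The 22 include the correlations of width and score, whose test does not show a relation beyond the calling itself. The count of 3791 regions became 1897 at scores from the median of 13.88 up and 949 at scores from 21.57 up, as those limits are built to do. At scores from 21.57 up, for the ratios a limit chosen after seeing the data, the X ratio was 0.70 (interval 0.43 to 1.02, exact binomial p = 0.0062) and the ratio of chromosome 4 fell to 0.79, below 1 (0 to 1.75, p = 0.823); the latter was 1.57 from the median score up, where the bootstrap interval, added after seeing the data, includes 1 (0.98 to 2.25), with an exact binomial p of 0.0355. The cause was not tested. The share with a neighbour stayed above random placement at 2 kb (53.6% against 8.46%), at 10 kb (77.6% against 42.2%) and from the median score up (49.6% against 10.0%). Pearson r of width and score over all sequences was 0.36 with the log10 of the score and 0.17 without the widest 1%, against 0.23. The excess of X regions on the background steps ranged from 38.7 to 49.5 percentage points over tolerances and score limits, which were added after seeing the data. No paired analysis was possible because the list has no value per library; leaving out a replicate could not be done for the same reason. Settings for transcription starts, gene lists and motifs were not run, as those tests were not. Depth per library is unknown, so a site missing from the list is not shown to be unbound.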

Other observations

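The values and tests in this part were chosen after the list had been seen. In the 1 Mb at the centromere end of the listed stretch of each arm, the number of regions differed between arms. It was 39 on 3R and 27 on 2L, against 28.6 and 29.8 regions per Mb of these whole arms, but 12 on 2R, 5 on X and 3 on 3L. Pooled, these 5 Mb held 86 regions, or 17.2 per Mb, against 27.7 per Mb in the rest of these arms (exact binomial test, p = 4.0e-06). Their median score was 10.9, against 12.8 elsewhere (permutation p = 0.0113). Both tests treat clustered regions as independent. The lower density does not hold for 3R, is slight on 2L, and rests on 2R, X and 3L. Of the 86, 4 scored at or above the 99th percentile of the rest, which 32 of 3117 regions there did. They lie on 2R at 936663 to 938871 (200.6) and 943613 to 944239 (97), on 3L at 24462044 to 24463747 (123.08) and on X at 22422249 to 22422863 (106.4). The first and the third are the highest of their arms, and those on 3L and X are the last regions of theirs.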
